A study of Mus musculus with 5 samples.

How the data were processed

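Messenger RNA from mouse E14 embryonic stem cells was sequenced in 5 libraries, with 1 library per group. The labels name normal cells and cells overexpressing hexokinase 2 (Hk2) and the M2 form of pyruvate kinase (Pkm2). Both kinds were cultured with leukemia inhibitory factor (LIF), or were kept 24 hours without LIF and then given LIF again. A further library came from overexpressing cells after 40 days without LIF. Libraries were made with a TruSeq RNA kit, per the labels' protocols. Kits of this kind do not mark strand, so reads of a gene and of an antisense or overlapping partner were not separated.

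The deposited table holds FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments) for each RefSeq transcript. The processing used TopHat2 2.0.7, Cufflinks 2.0.2 and the mm9 genome build, per the submitters' processing notes. Other settings, including the treatment of fragments that fit several places, are not given in the sources used here, so values of genes with near-identical copies, such as Rps3a1 and Tuba1b, are uncertain. The authors normalized FPKM for transcript length and library depth, so the values are not counts and no count model was run on them. The table has 28698 transcripts, of which 355 carry a suffix for a further copy. A hyphen stands in 610 cells of 353 transcripts, and its meaning is not given in the sources used here.

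Transcripts were paired with gene symbols by accession in a RefSeq table of assembly GRCm38.p6, which was used for names and for which genes overlap. Symbols were found for 28066 transcripts and not for 632, of which 128 had a mean FPKM of at least 1. FPKM was summed over the transcripts of a gene, giving 22267 genes. The 337 genes with a hyphen in any transcript were left out. Coordinates are those of the GENCODE vM1 annotation on NCBIM37, the assembly also called mm9.

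Ratios were taken between log2(FPKM + 1) values of 2 libraries, which understates the change of genes with low FPKM. Genes with a mean FPKM of at least 1 over the 5 libraries were kept, 9590 in all. With 1 library per group no difference between 2 libraries has a replicate check, so genes at least 2-fold different were counted without a test. In these 9590 genes an exact 0 occurs in at least 1 library for 749 genes, among them genes that every cell uses, such as Tubb4b and Tuba1b. A 0 of this kind can be a failed estimate, so a gene named for such a value is described as listed at 0. List medians and counts of 2-fold differences still include such genes, unless the text says otherwise. The 8841 genes above 0 in every library are given as a further set, which was chosen after the values were seen.

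Limma 3.58.1 (R 4.3.3; lmFit, then eBayes with trend) was run on the 4 libraries of the cell type by culture layout, with both factors in the model and Benjamini-Hochberg adjustment. This leaves 1 residual degree of freedom, to which limma added 1.46 prior degrees of freedom. The residual is the interaction of cell type and culture together with library noise. Nothing shows that the 2 libraries of a cell type come from separate lines, so a p-value here measures agreement across these 2 cultures only. In simulated data with the spread limma fitted to these libraries, 9590 genes were run for the cell type comparison and 50 genes were changed by each size of fold. None of the genes changed 2-fold, 4-fold, 8-fold or 16-fold passed an adjusted p of 0.05, and the median estimate for the 4-fold set was 1.98 on the log2 scale. With the spread multiplied by 0.1, 98.0% of the genes changed 2-fold and 92.0% of those changed 4-fold passed.

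Before the data were examined, 32 gene lists were fixed, covering metabolic pathways, pluripotency states, early lineages, other cell types, stress and proliferation. For each list with at least 3 members past the filter, the median log2 ratio was placed among 10000 random lists of the same size, matched on mean log2(FPKM + 1) in 10 bins. The percentile describes these libraries and is not a test across replicates. A simulated list of 20 genes shifted by 1 on the log2 scale came out with a median of 0.89 and a percentile of 100. For limma, the count of members passing is also given adjusted over the list alone. That adjustment does not cover the number of lists or of comparisons.

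Genes to be named were set by rule before the data were examined. The rule takes Hk2 and Pkm2 (now Pkm), the 8 highest and 8 lowest ratios of each comparison without clone names and small RNAs, the 8 largest limma changes in each direction, a short set of pluripotency and lineage genes, and up to 4 members of each list with the largest ratios. Under it, 93 of the 96 genes named for their ratio were listed at 0 in a library of the pair. Further choices were therefore made after the values were seen: the 10 highest and 10 lowest ratios among genes above 0 in every library, and the 12 genes per direction with the largest value of the smaller ratio where both cultures, or both cell types, moved the same way. Other list members outside the rule were also named after their values were seen.

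FPKM values near 0 fall on steps set by whole fragments. From 2426 genes with a single transcript of at least 2000 bases, and an assumed fragment length of 150 bases, the steps below 0.2 FPKM place the depth at about 41100000, 42500000, 39100000, 37500000 and 40200000 fragments in the order normal with LIF, overexpressing with LIF, normal after withdrawal, overexpressing after withdrawal and 40 days. At these depths 1 fragment on a transcript of 1 kb is worth 0.0235 to 0.0266 FPKM. These depths are estimates, since the table gives no counts, and cover no biological variation.

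Alternatives tried were pseudocounts of 0.1 and 5, no filter beyond an FPKM above 0 in 1 library, a mean FPKM of at least 5, scaling of libraries by the median of ratios, quantile normalization, a threshold of 3-fold, eBayes without trend and limma without the covariate. Added after the data were seen were leaving out genes listed at 0, keeping only genes with 1 transcript that were never at 0, and counting hyphens as 0. A count was taken as unchanged within 1.5 times, a correlation within 0.1, and a list median or gene ratio within 0.5 on the log2 scale. Tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures with matplotlib 3.10.9.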

Results

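RNA from mouse E14 embryonic stem cells was measured by sequencing in 5 libraries, 1 for each combination of cell type and culture described in the labels. The series asks how the transcriptome of cells overexpressing Hk2 and Pkm2 differs from that of normal E14 cells, with LIF, the cytokine that holds mouse embryonic stem cells undifferentiated, and after its removal. Between 10151 and 11114 transcripts reached 1 FPKM per library. The depth behind them was estimated at 37500000 to 42500000 fragments. No group has a replicate, so no difference between 2 libraries below has a replicate check.

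Hk2, which phosphorylates glucose in the first step of glycolysis, stood at 76.2 FPKM in normal cells with LIF and 98.6 FPKM in the library labelled as overexpressing, a ratio of 1.29. After the 24 hour withdrawal it stood at 49.7 and 59.0 FPKM, a ratio of 1.19, and at 40 days without LIF at 29.0 FPKM. Pkm, whose M2 form catalyses the last step of glycolysis, stood at 510 and 567 FPKM with LIF and at 611 and 564 FPKM after withdrawal, so that the library labelled as overexpressing was the lower there. At 40 days Pkm stood at 495 FPKM. Hk2 lies on chromosome 6 from 82675019 to 82724448 on the minus strand, and Pkm on chromosome 9 from 59504383 to 59527182 on the plus strand (mm9). Both are protein-coding. Pkm has 1 transcript in the table, so its M1 and M2 forms were not separated, and whether reads of the introduced genes would count there is not given in the sources used here. Neither gene differed 2-fold between the labelled cell types in either culture, so each such library is named by its label only.

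**Figure D1:**
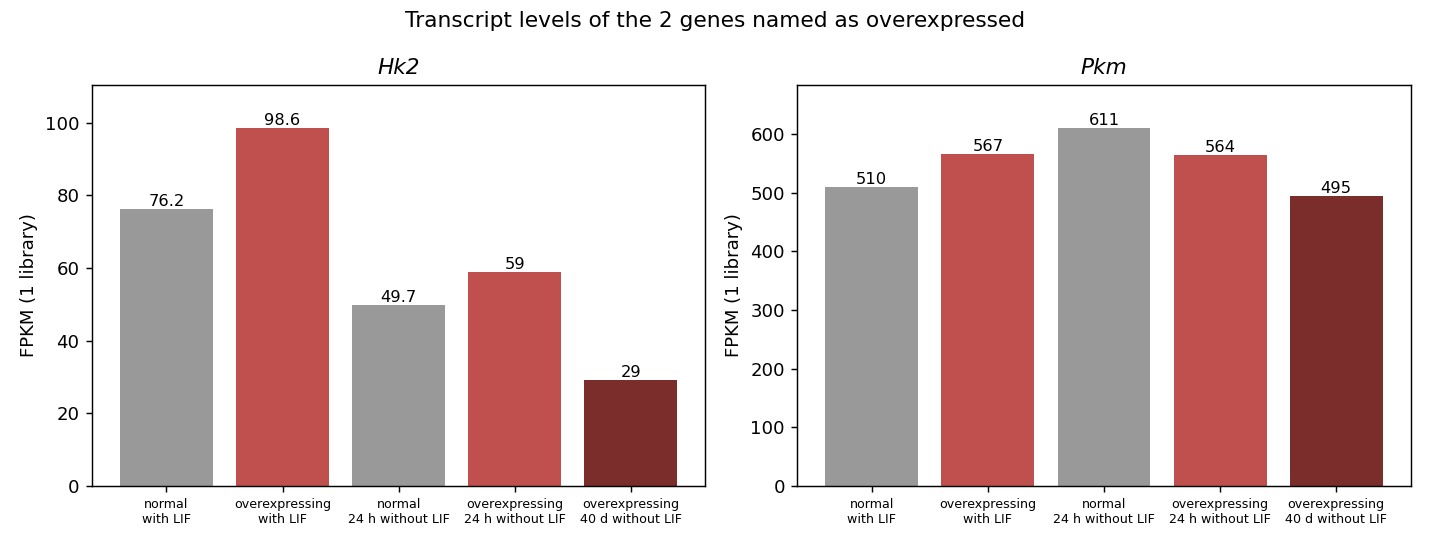
FPKM of Hk2 (left) and Pkm (right) in each of the 5 libraries, 1 bar per library, with the axis from 0 and no error bars because each group has 1 library. Hk2 runs from 98.6 FPKM in overexpressing cells with LIF to 29.0 FPKM at 40 days, and Pkm stays between 495 and 611 FPKM.

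With LIF, the library labelled as overexpressing was lower than normal cells in Y-linked transcripts and in targets of p53, the damage-responsive transcription factor. Ddx3y, a Y-linked RNA helicase, stood at 11.8 FPKM in normal cells and 0.0225 FPKM in the overexpressing library. Uty, a Y-linked relative of a histone demethylase, stood at 3.25 and 0.0097 FPKM. The 17 p53 targets had a median log2 ratio of -0.54, at percentile 0.01 of matched random lists, with 6 at least 2-fold lower and none higher. Ptpn14 (-1.63), Perp (-1.46), Mdm2 (-1.42) and Bax (-1.27) had the largest ratios among them. Epithelial and mesenchymal genes had a median of -0.64 at percentile 0.01, with Cldn7 (-1.77), Crb3 (-1.50) and Epcam (-1.34) lowest. Of the 11 members past the filter, 8 were below 0 and 3 above. The list joins markers of both states, so its medians, here and below, give no direction between them. The pluripotency genes Pou5f1 (1092 and 1084 FPKM), Nanog (150 and 183 FPKM) and Sox2 (212 and 236 FPKM) were at similar levels.

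Among metabolic lists with LIF, serine, glycine and 1-carbon genes had a median log2 ratio of 0.21 at percentile 99.9 and hypoxia targets of 0.27 at percentile 99.6. The 19 glycolytic genes other than Hk2 and Pkm had a median log2 ratio of 0.074 at percentile 97.1, with 4 at least 2-fold higher and 1 lower, among them Eno2 and Aldoc, listed at 0 in a library of the pair. Slc2a3, a glucose transporter, stood at 65.7 and 193 FPKM, and Slc16a3, a lactate exporter, at 11.9 and 29.3 FPKM. Pentose phosphate genes had a median of -0.23 at percentile 7.82, the tricarboxylic acid cycle -0.11 at percentile 26.5, nuclear respiratory chain genes -0.12 at percentile 12.9 and cholesterol synthesis -0.19 at percentile 7.69. Replication histones had a median of -0.30 at percentile 0.90, and ribosomal proteins -0.27 at percentile 0.06. Between cell types after withdrawal these 2 medians were 0.021 and 0.011. The 10 reference genes had a median of -0.096 at percentile 38.5, a sign that quantile normalization turned. Also outside the middle 95% of random lists were trophoblast (-0.82 at percentile 1.14), imprinted (-0.26 at percentile 2.465), immediate early (-0.35 at percentile 0.46) and interferon genes (0.23 at percentile 98.15). Only 4 of the 17 trophoblast members passed the filter, here and in the medians below, so they do not stand for the whole list.

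Of 9590 genes, 394 were at least 2-fold higher and 510 lower with LIF, 9.43% in all. Of these 904 genes, 314 were listed at 0 in a library of the pair, and so were all 16 genes with the most extreme ratios, such as Tubb4b (398 FPKM, listed at 0 in normal cells) and Snhg1 (160 FPKM, listed at 0 in the overexpressing library). Among the 8841 genes never listed at 0, 541 were 2-fold different, with 224 higher and 317 lower, and 95% of their log2 ratios lay between -1.16 and 1.001. The highest of these were Shmt1 (3.14), Ppp1cb (2.96), Smc2 (2.86) and Dicer1 (2.75), and the lowest Ddx3y (-3.64), Rps3a1 (-3.47), Snrpc (-3.00) and F11r (-2.91). Shmt1 and Rps3a1 did not keep these sizes across both cultures, at 1.67 ± 0.94 and -0.037 ± 2.19 (SE, limma, 4 libraries).

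After the 24 hour withdrawal, the library labelled as overexpressing again had Ddx3y and Uty near 0, at 0.013 and 0.0113 FPKM against 11.8 and 3.74 FPKM in normal cells. The 17 p53 targets had a median of -0.71, below all 10000 random lists, with 5 at least 2-fold lower and 1 higher, and Perp (-2.48), Ptpn14 (-1.96) and Aen (-1.66) lowest, while Bax (0.017) did not differ as it had with LIF. Genes of the primed epiblast, the state that follows naive pluripotency, had a median of 0.32 at percentile 99.9, with 6 at least 2-fold higher, 1 of them listed at 0 in normal cells, and 3 lower. Dnmt3b, a de novo DNA methyltransferase on chromosome 2 from 153475186 to 153513466, stood at 31.7 FPKM in normal cells and 144 FPKM in the overexpressing library, while Fgf5 stood at 0.52 and 3.56 FPKM. LIF targets had a median of -0.39 and naive pluripotency genes of -0.33, both at percentile 0.03, with Dppa3 (-1.49) lowest of the second. Fibroblast and feeder genes had a median of -0.70, below all 10000 random lists, with 5 at least 2-fold lower, such as Ccn1 (-2.02), Ccn2 (-1.19) and Lgals1 (-1.13), and 1 higher. With LIF their median had been -0.11 at percentile 27.5.

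The serine, glycine and 1-carbon list again had a higher median in the overexpressing library, 0.24 at percentile 99.9, with Phgdh at 2.81 and 10.7 FPKM and Psat1 at 52.7 and 103 FPKM. Glycolysis (0.0021 at percentile 54.5), the tricarboxylic acid cycle (-0.031 at percentile 29.9) and the respiratory chain (0.020 at percentile 68.1) lay close to 0. Slc16a3 stood at 27.4 and 61.8 FPKM, and Slc2a3, higher in the overexpressing library with LIF, was lower here at 52.1 and 38.0 FPKM. Hypoxia targets, above the random lists with LIF, had a median of -0.047 at percentile 48.9. Cell cycle genes had a median of 0.088 at percentile 96.6. Trophoblast (4 members, -0.74 at percentile 1.83), epithelial and mesenchymal (-0.40 at percentile 0.62) and germline genes (0.34 at percentile 98.2) also lay outside the middle 95% of random lists.

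Over all genes 402 were at least 2-fold higher and 497 lower after withdrawal, 9.37% of 9590, and 300 of these 899 were listed at 0 in a library of the pair. All 16 genes with the most extreme ratios were listed at 0, among them Tuba1b (1605 FPKM, listed at 0 in normal cells). Among genes never listed at 0, 223 were higher and 327 lower. The highest were Rps3a1 (3.40), Ap1g1 (3.05), Me2 (2.99) and Mtdh (2.97), and the lowest Ddx3y (-3.66), Sfmbt2 (-3.37), Vcl (-2.77) and Tgm1 (-2.75). Rps3a1 and Vcl did not keep these sizes across both cultures, at -0.037 ± 2.19 and -0.12 ± 1.7 (SE, limma, 4 libraries).

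Across both cultures, Ddx3y, Uty and Eif2s3y were lower in the libraries labelled as overexpressing by 3.65 ± 0.16, 2.15 ± 0.16 and 0.82 ± 0.15 on the log2 scale (SE, limma, 4 libraries). All 3 passed when adjusted over the list alone, at limma adjusted p values of 0.00185, 0.0034 and 0.0216, and none over all genes. Of the 12 fibroblast and feeder genes, 4 passed adjusted over the list alone: Ccn1 (-1.82 ± 0.17), Ccn2 (-1.26 ± 0.085) and Lgals1 (-1.13 ± 0.072) fell and Thy1 (1.11 ± 0.18) rose. Slc16a3 rose by 1.19 ± 0.084 as the only one of 19 glycolytic genes. Of the 4 trophoblast genes past the filter, Tfap2c (-1.20 ± 0.16) and Krt8 (-0.87 ± 0.16) passed, both lower. In the other 28 of 32 lists no gene passed. The adjustment over a list alone did not cover the number of lists. Genes chosen after their values were seen, for large ratios of the same direction in both cultures, included Pttg1, an inhibitor of chromatid separation (8.12 to 58.9 FPKM with LIF, 7.82 to 61.1 FPKM after withdrawal), Mydgf, Ntpcr and Metap2, which were higher, and Chchd4, a mitochondrial import factor (72.7 to 13.3 and 63.5 to 13.2 FPKM), Polr1c and Kmt5a, which were lower. Over all 9590 genes limma called 0 genes for cell type, with 918 at an unadjusted p under 0.05 and a smallest adjusted p of 0.512. In the simulation with the fitted spread even genes changed 16-fold did not pass, so this count does not show absence of change. A p-value here measures agreement over these 2 cultures only.

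The log2 ratios of cell type in the 2 cultures, which share no library, correlated weakly across genes (Pearson 0.101, Spearman 0.289). Genes are not independent replicates, so no p-value is given. Among genes never listed at 0 the Pearson value was 0.245, with 29 genes at least 2-fold higher in both cultures, 69 lower in both and 42 in opposite directions, against 5.65, 11.7 and 16.3 if the 2 sets were independent.

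**Figure D2:**
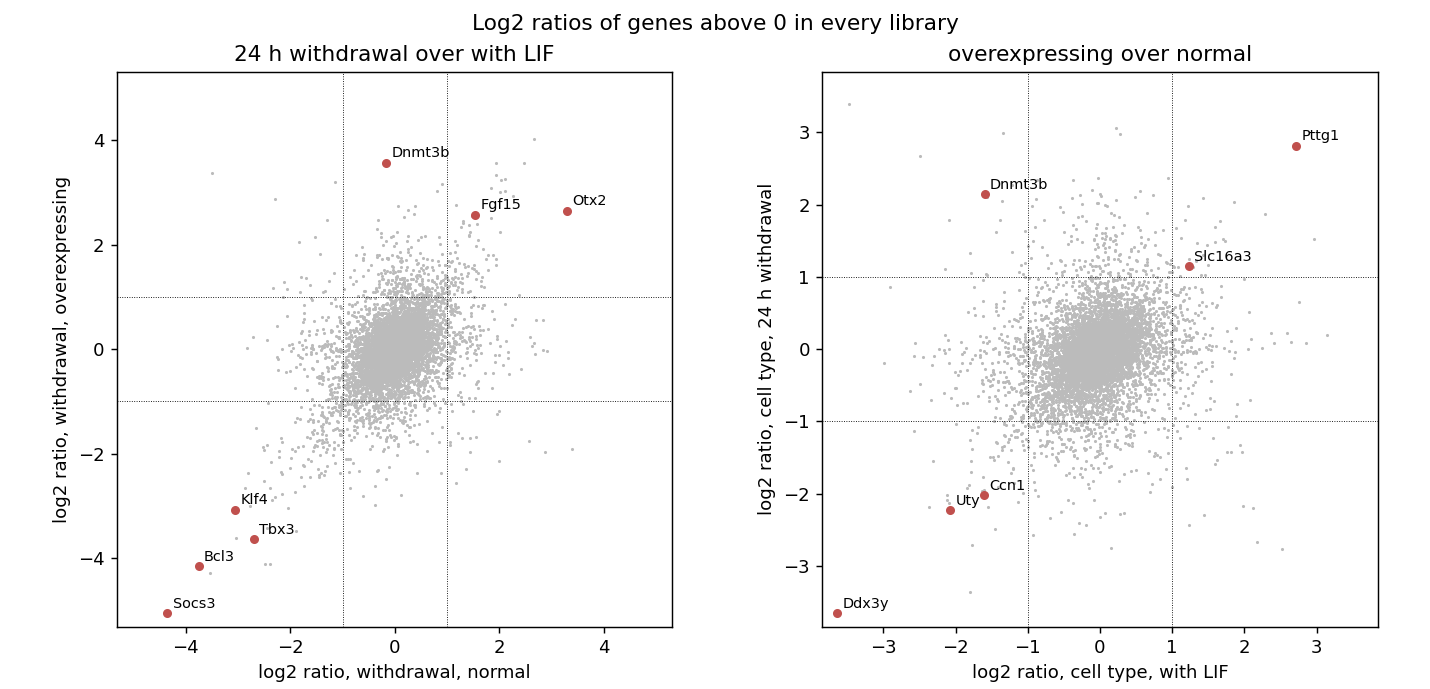
Log2 ratios of FPKM + 1 for the 8841 genes above 0 in every library, 1 point per gene, with dotted lines at 2-fold. Left, 24 hour withdrawal over culture with LIF in normal (horizontal) and overexpressing (vertical) cells, where Socs3 lies at -4.35 and -5.06; right, overexpressing over normal with LIF (horizontal) and after withdrawal (vertical), where Ddx3y lies at -3.64 and -3.66.

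In normal cells the 24 hour withdrawal, although followed by LIF according to the label, went with low transcripts of LIF targets and naive pluripotency genes and high transcripts of primed epiblast genes. Socs3, the feedback inhibitor of LIF signalling on chromosome 11 from 117827393 to 117831361, stood at 65.3 FPKM with LIF and 2.25 FPKM after withdrawal. The 18 LIF targets had a median log2 ratio of -1.69 and the 20 naive genes of -1.14, both below all 10000 random lists, with 14 and 11 members at least 2-fold lower and none higher. Bcl3 (-3.75), Klf4 (-3.06) and Tbx3 (-2.70) were among the lowest. The 17 primed genes had a median of 1.003, above all random lists, with 9 higher and 1, Dnmt3a, listed at 0 after withdrawal, and Otx2, a homeobox factor of the epiblast, stood at 1.20 and 20.7 FPKM. Pou5f1 (1092 and 987 FPKM) and Sox2 (212 and 175 FPKM) differed little, and Nanog stood at 150 and 59.3 FPKM.

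Among metabolic lists, glycolysis had a median of 0.30 at percentile 99.99, with 5 of 19 genes at least 2-fold higher and 1, Aldoc, listed at 0 after withdrawal, Pfkl at 12.1 and 67.1 FPKM and Pfkm at 8.78 and 22.7 FPKM. The glucose transporter Slc2a1 stood at 160 and 113 FPKM, and Ldha at 418 and 519 FPKM. The respiratory chain (-0.24 at percentile 0.01) and serine, glycine and 1-carbon genes (-0.35 at percentile 0.04) had lower medians, the latter with Tdh, threonine dehydrogenase, at 225 and 89.4 FPKM. Replication histones (-0.33 at percentile 0.26) and ribosomal proteins (-0.17 at percentile 0.40), which can follow RNA or library quality, were lower by a similar size. Both lists were also lower between cell types with LIF, a comparison that shares the normal library with LIF. Their lower medians in both comparisons may therefore rest on that 1 library, which was not tested. The ATF4 list (-0.10 at percentile 16), cholesterol synthesis (0.010 at percentile 64.2) and the reference genes (0.062 at percentile 89.0) stayed within the range of random lists. Trophoblast (4 members, -1.36 at percentile 0.23) and immediate early genes (-0.23 at percentile 1.97) lay below the middle 95% of random lists. Fibroblast and feeder (0.28 at percentile 98.96), epithelial and mesenchymal (0.40 at percentile 99.6), imprinted (0.20 at percentile 97.97) and germline genes (0.43 at percentile 97.8) lay above that range. In all, 443 genes were at least 2-fold higher and 528 lower, of which 304 were listed at 0 in a library of the pair, and all 16 extreme genes were of this kind. Among genes never listed at 0, 277 were higher and 341 lower. Vcl (3.39), Otx2 (3.30), Shmt1 (2.91) and Txnl1 (2.87) were highest, and Socs3 (-4.35), Bcl3 (-3.75), Spink1 (-3.54) and Rps3a1 (-3.49) lowest. Not all of these recurred in overexpressing cells. Across both cell types Vcl changed by 0.74 ± 1.7, Shmt1 by 1.44 ± 0.94, Txnl1 by 0.45 ± 1.55 and Rps3a1 by -0.058 ± 2.19 (SE, limma, 4 libraries).

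In the libraries labelled as overexpressing, the same withdrawal went with lower Socs3 (64.8 and 0.97 FPKM), Bcl3 (34.9 and 1.005 FPKM), Tbx3 (50.7 and 3.15 FPKM) and Klf4 (63.5 and 6.66 FPKM). The median was -2.03 for LIF targets and -1.72 for naive genes, both below all random lists, with 13 members of each at least 2-fold lower and 1 naive gene, Lefty1 (1.24), higher. Primed genes had a median of 2.14, above all random lists, with 11 of 17 at least 2-fold higher and 1 lower. Dnmt3b stood at 11.2 and 144 FPKM, Sall2 at 1.13 and 17.0 FPKM, and Lef1, a Wnt pathway factor, at 0.202 and 8.16 FPKM. Immediate early genes had a median of -0.51, below all random lists, with 4 of 14 at least 2-fold lower and 1 higher. Glycolysis had a median of 0.20 at percentile 98.8 and general pluripotency genes of 0.28 at percentile 99.9. The respiratory chain (-0.13 at percentile 0.03) and serine, glycine and 1-carbon genes (-0.18 at percentile 1.53) had lower medians, while replication histones (-0.041 at percentile 31.8) and ribosomal proteins (0.0996 at percentile 92.2) lay within the range of random lists. Lower medians also held for the ATF4 list (-0.21 at percentile 1.43), trophoblast genes (-1.40 at percentile 0.27) and mesoderm genes (-1.44 at percentile 0.26, and -0.54 without Pecam1, listed at 0 after withdrawal), and germline genes had a higher median, 0.55 at percentile 98.75.

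Over all genes 555 were at least 2-fold higher and 582 lower in the libraries labelled as overexpressing, and 308 of these 1137 were listed at 0 in a library of the pair, among them all 16 extreme genes. Among genes never listed at 0, 371 were higher and 401 lower, with Pim2 (4.02), Dnmt3b (3.57), Vrtn (3.56) and Enpp2 (3.56) highest and Socs3 (-5.06), Spink1 (-4.28) and Bcl3 (-4.16) lowest. Whether normal and overexpressing cells responded differently was not tested, because the interaction is the residual of the only fit.

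Across both cell types, 14 of 18 LIF targets passed in limma when adjusted over the list alone, 13 of which fell. Socs3 fell by 4.71 ± 0.25, Bcl3 by 3.96 ± 0.18 and Klf4 by 3.07 ± 0.090 on the log2 scale (SE, 4 libraries), with Myc the exception at 0.50 ± 0.087. Lifr, among the 13, was listed at 0 in both libraries after withdrawal. Of 20 naive genes 11 passed, all lower, including Esrrb (-1.63 ± 0.11) and Zfp42 (-1.14 ± 0.072). Of 17 primed genes 9 passed, all higher, including Otx2 (2.98 ± 0.25) and Lef1 (2.60 ± 0.26). Klf4, Klf5 and Tfcp2l1 passed in both the LIF target and naive lists, and Junb in both the LIF target and immediate early lists. The counts of these lists are therefore not separate. In glycolysis Pfkm (1.36 ± 0.11), Pfkp, Tpi1, Ldhb and Slc16a3 rose and Slc2a1 (-0.46 ± 0.074) fell, adjusted over the list alone, while Hk2 fell by 0.67 ± 0.079. Further genes passing in this way included Tdh (-1.36 ± 0.073), Idh3b (1.51 ± 0.077), the imprinted growth inhibitor Cdkn1c (1.79 ± 0.092), Ccnd3 (-1.23 ± 0.070) and Cdh1 (1.32 ± 0.13). S100a6 of the feeder list (-2.56 ± 0.19), Sox7 of the endoderm list (-1.48 ± 0.16) and Phlda2 (-0.70 ± 0.074) fell. Lrp2 of the endoderm list (1.77 ± 0.18), Sox11 of the neural list (1.32 ± 0.22) and Peg10 (0.77 ± 0.072) rose. All 4 trophoblast genes past the filter passed, with Tfap2c (-1.94 ± 0.16), Tead4 (-1.97 ± 0.20) and Krt8 (-0.92 ± 0.16) lower and Ascl2 (0.74 ± 0.20) higher, and of the immediate early genes Junb (-2.27 ± 0.10), Fos (-1.48 ± 0.18), Egr1 and Ier2 fell and Dusp4 and Etv5 rose. Meg3 and Tubb3 also passed, but rest on values listed at 0 after withdrawal. In total 15 of the 32 lists held a gene passing over the list alone. That adjustment did not cover the number of lists, and how many random lists would hold such a gene was not determined. At an unadjusted limma p under 0.05 were 2 of 25 tricarboxylic acid cycle and 4 of 26 cell cycle genes, against 1154 of all 9590. Idh3b and Ccnd3 therefore do not show a change of their lists. Over all 9590 genes limma called 0 genes for withdrawal, with 1154 at an unadjusted p under 0.05 and a smallest adjusted p of 0.32. This count comes from the same fit, with the same fitted spread, as that for cell type and does not show absence of change either. The withdrawal ratios of the 2 cell types correlated across genes at 0.210 (Spearman 0.345), and at 0.416 among genes never listed at 0, where 90 genes were higher in both, 147 lower in both and 38 in opposite directions, against 11.6, 15.5 and 26.9 if independent.

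At 40 days without LIF, the library labelled as overexpressing had high transcripts of primitive and visceral endoderm, the first extraembryonic endoderm, compared with the same label with LIF. The list had a median log2 ratio of 3.35, above all random lists. Of its members 13 of 16 were at least 2-fold higher, and 1, Sparc, was listed at 0 at 40 days and at 74.3 FPKM with LIF. Only 16 of the 23 members in the table passed the filter. The filter's mean includes the 40 day library, so members near 0 with LIF could pass through that library alone. The count and the percentile are therefore no independent support for a rise at 40 days. Dab2, an endocytic adaptor, stood at 0.276 and 52.0 FPKM, Cubn, an endocytic receptor, at 0.0896 and 40.1 FPKM, the basement membrane collagens Col4a1 and Col4a2 at 4.87 and 125 FPKM and at 1.88 and 60.9 FPKM, and the transcription factors Gata4 and Gata6 at 1.19 and 25.6 FPKM and at 0.248 and 7.88 FPKM. Naive genes had a median of -2.25, below all random lists, with 14 of 20 lower and Lefty1 (3.51) higher, while Pou5f1 stood at 1084 and 807 FPKM, Nanog at 183 and 29.6 FPKM and Zfp42 at 278 and 40.9 FPKM. Primed genes had a median of 1.74, above all random lists, with Fgf5 at 0.0329 and 7.46 FPKM.

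Genes of the ATF4 response to amino acid and endoplasmic reticulum stress had a median of 1.65, above all random lists, with 8 of 15 at least 2-fold higher. Atf3 stood at 0.502 and 30.9 FPKM, Chac1 at 5.75 and 100.4 FPKM, Herpud1 at 10.5 and 80.4 FPKM and Nupr1 at 5.80 and 43.1 FPKM, while the chaperone Hspa5 stood at 182 and 118 FPKM. Germline genes (1.45 at percentile 99.5, with Mael at 0.600 and 12.3 FPKM), imprinted genes (0.83 at percentile 99.98, with Cdkn1c at 8.11 and 69.2 FPKM), epithelial and mesenchymal genes (1.01 at percentile 99.8, with Cldn7 at 0.959 and 32.9 FPKM) and p53 targets (0.55 at percentile 99.7, with Pmaip1 at 0.0791 and 13.2 FPKM) had higher medians. LIF targets (-1.47, below all random lists), immediate early genes (-0.46 at percentile 0.70), general pluripotency (-0.37 at percentile 2.94) and cholesterol synthesis (-0.37 at percentile 0.89) had lower medians. Glycolysis (0.14 at percentile 89.5) lay within the random lists, although Slc2a1 stood at 151 and 46.9 FPKM. Ribosomal proteins had a median of 0.17 at percentile 99.2 and replication histones of 0.081 at percentile 17.7. The mesoderm (0.59 at percentile 77.4), neural (0.33 at percentile 62.8) and trophoblast (-0.32 at percentile 9.91) lists had few members past the filter, 4, 6 and 4. The neural list had 3 at least 2-fold higher and 1 lower, and a median of 1.16 without Tubb3, which was listed at 0 in normal cells after withdrawal. Fibroblast and feeder genes had a median of 0.996 at percentile 99.94, with 6 of 12 at least 2-fold higher and 2 lower, and of 0.571 without Tagln, which was listed at 0 with LIF. T, a marker of the primitive streak, stood at 0.133 and 0.242 FPKM.

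At 40 days 1343 genes were at least 2-fold higher and 797 lower, 22.3% of 9590, and 367 of these were listed at 0 in a library of the pair, as were 15 of the 16 extreme genes. Among genes never listed at 0, 1079 were higher and 598 lower, with Dab2 (5.38), Pim2 (5.29), Cldn6 (4.90) and Car4 (4.80) highest and Socs3 (-4.72), Hmgn2 (-4.65), Bmp4 (-3.96) and Inhbb (-3.71) lowest. The median ratio of all genes was 0.076.

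**Figure D3:**
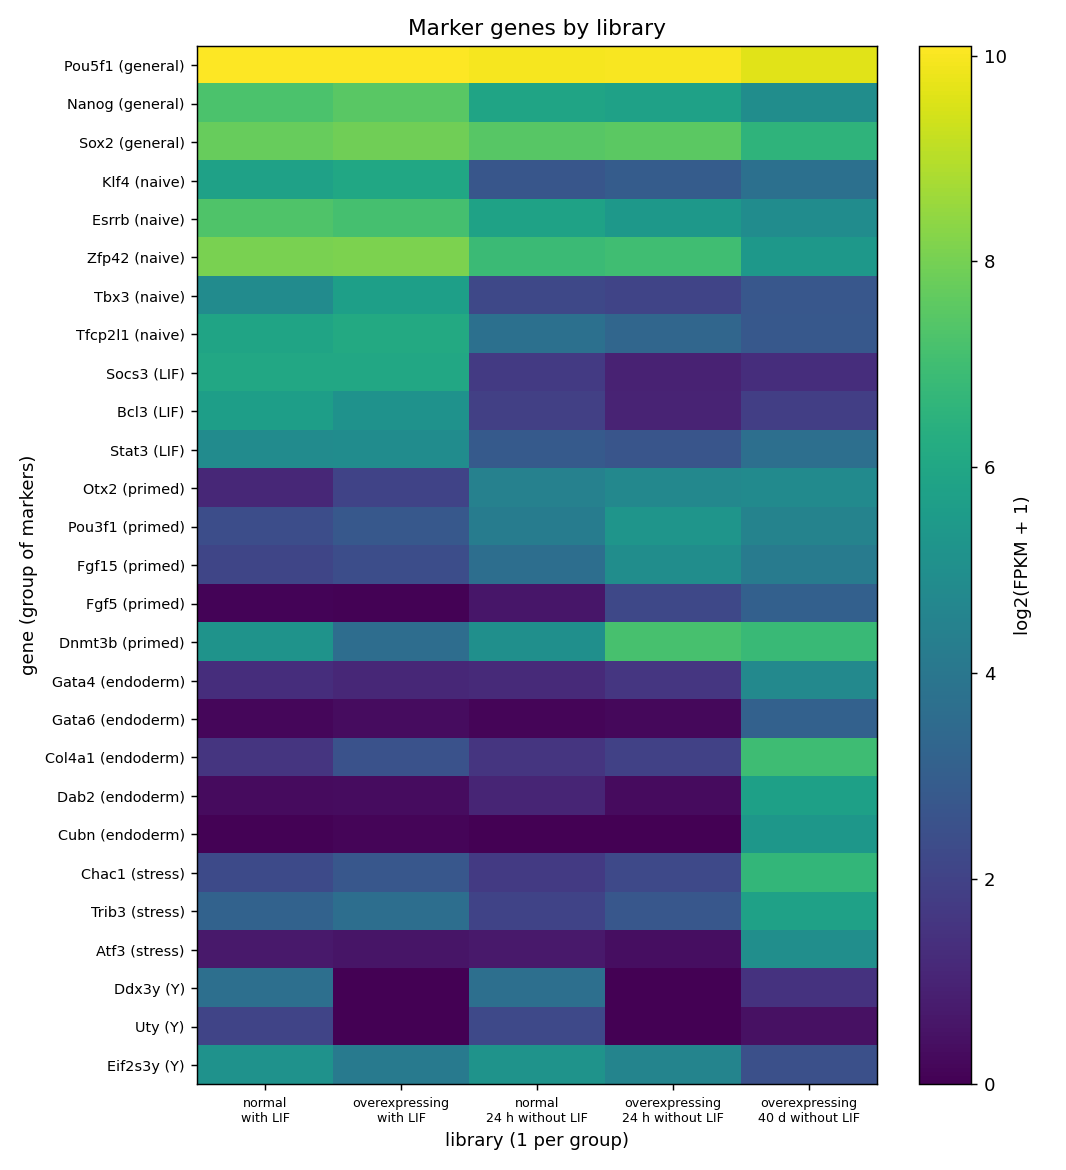
Heatmap of log2(FPKM + 1), as the colour scale, for marker genes (rows, group in brackets) in the 5 libraries (columns, 1 per group). Socs3 goes from 65.3 FPKM in normal cells with LIF to 2.25 FPKM after withdrawal, and Col4a1 reaches 125 FPKM in the 40 day library only.

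The comparison with normal cells with LIF shares the 40 day library with the one above, and cell type and time differ together in it. In it endoderm genes again had a median of 3.35, above all random lists, with 13 of 16 higher. The limit of the filter given above applies here too, and to the other lists at 40 days. Lrp2, an endocytic receptor, stood at 1.26 and 46.7 FPKM, and the collagen chaperone Serpinh1, which is in no list, at 5.69 and 162 FPKM. The p53 targets had a median of -0.18 at percentile 20.1, where the comparison with the same label gave 0.55. Fibroblast and feeder genes had a median of 0.755 at percentile 99.7, and of 0.10 without Tagln. Replication histones had a median of -0.23 at percentile 0.76 and ribosomal proteins of -0.13 at percentile 55.1. Naive genes had a median of -1.88, LIF targets of -1.35, primed genes of 1.65 and the ATF4 list of 1.22, each outside all random lists. Epithelial and mesenchymal genes had a median of 0.47 at percentile 95.25, within the middle 95% of random lists. Serine, glycine and 1-carbon genes (0.57 at percentile 99.97), imprinted (0.52 at percentile 99.1) and germline genes (1.36 at percentile 99.65) lay above it. The respiratory chain (-0.40 at percentile 0.74), cholesterol synthesis (-0.605 at percentile 0.16), general pluripotency (-0.51 at percentile 1.44) and trophoblast genes (4 members, -1.24 at percentile 0.51) lay below that range. Ddx3y stood at 11.8 and 1.79 FPKM, Uty at 3.25 and 0.369 FPKM and Eif2s3y at 34.1 and 4.58 FPKM. In all 1265 genes were at least 2-fold higher and 871 lower, 22.3% of 9590, with 357 of these listed at 0 in a library of the pair, as were 14 of the 16 extreme genes. The direction of this excess depended on the filter, since 566 were higher and 615 lower among genes with a mean FPKM of at least 5.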

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

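Among 412 members of the fixed lists and always-named genes that were never listed at 0, 1 had cell type ratios of at least 2-fold in opposite directions in the 2 cultures. Among all 8841 genes never listed at 0, 42 had such ratios, so a pair of this kind is not particular to the flagged gene. Dnmt3b was lower in the library labelled as overexpressing with LIF (35.8 and 11.2 FPKM, log2 ratio -1.60) and higher after the 24 hour withdrawal (31.7 and 143.6 FPKM, log2 ratio 2.15), so that the log2 ratios differ by 3.74. The difference was not tested, since each value rests on 1 library per group. At 40 days the library labelled as overexpressing stood at 114.2 FPKM.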

How the results depend on the processing

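The 2 limma counts were 0 under every alternative run. In the simulated cell type comparison with the fitted spread, none of the genes changed up to 16-fold passed. In the same layout with the spread multiplied by 0.1, 98.0% of the genes changed 2-fold and 92.0% of those changed 4-fold passed. A count of 0 therefore goes with the fitted spread and not with the layout alone. It shows neither stability nor absence of change. More than 50 changed genes per size of fold were not simulated. At an unadjusted limma p under 0.05 there were 663 to 1463 genes for cell type and 940 to 1865 for withdrawal. Smallest limma adjusted p values ran from 0.121 to 0.579. No list median or named gene ratio of at least 1 in size changed sign. The limma fit compared cell types within culture and withdrawal within cell type, and without the covariate it also gave 0 genes. Leaving 1 of the 4 libraries out of limma would leave no residual degree of freedom. Counts of genes at least 2-fold different are given in the order cell type with LIF, cell type after withdrawal, withdrawal in normal cells, withdrawal in overexpressing cells, 40 days, and 40 days over normal cells. They were 904, 899, 971, 1137, 2140 and 2136. A pseudocount of 5 gave 350, 364, 408, 489, 972 and 986, a mean FPKM of at least 5 gave 500, 489, 552, 652, 1168 and 1181, and a 3-fold threshold gave 408, 414, 462, 545, 1074 and 1012, each by its construction stricter or on fewer genes. Added after the data were seen, leaving out genes listed at 0 gave 541, 550 and 618 in the first 3, and genes with 1 transcript never at 0 gave 422, 430, 489, 592, 1289 and 1296. Other alternatives stayed within 1.5 times. At 40 days 62.8% of the genes were higher, and 52.3% (1098 higher, 1002 lower) after quantile normalization, which moved the median of all genes by -0.107. Over normal cells 1265 were higher and 871 lower, against 566 and 615 with a mean FPKM of at least 5 and 1108 and 1023 after quantile normalization. The correlation of cell type ratios was 0.245 without genes at 0 and 0.234 with single transcripts never at 0, against 0.101, and that of withdrawal ratios 0.416 and 0.401, against 0.210. List medians of at least 1 in size numbered 12 with a pseudocount of 5, against 26, as a larger pseudocount shrinks log2 ratios by its construction. Named gene ratios moved by 0.5 or more in 398 cases with a pseudocount of 0.1 and 592 with 5, and in none under the other alternatives. Of those others, only scaling by the median of ratios and quantile normalization could move a ratio. The rest change only which genes are kept. Depth limits genes near 0.0235 to 0.0266 FPKM per fragment on 1 kb.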

Other observations

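Of the genes of the 2-cell-like state only Gm4340 passed the filter, at 6.40 FPKM at 40 days. It is listed at 0 in the overexpressing library with LIF.

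The test of overlapping genes was chosen before its result was seen, and the other tests below after the patterns were seen. No autosome stood apart as a whole chromosome: with LIF the medians of autosomes between cell types ran from -0.15 to -0.011 on the log2 scale, against 0.585 for a gained copy.

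Genes listed at 0 in some libraries and at 10 FPKM or more in another numbered 251. Too few fragments do not account for this, since a median of 440 fragments would have been expected in the library at 0, over the 223 of these genes with a known length. Genes with 1 transcript were affected 1.42 times as often as genes with several (4.73% and 3.33%). This comparison cannot decide whether fragments moved between transcripts of the same gene. FPKM was summed over transcripts before a 0 was sought, so a move between summed transcripts would leave the sum above 0. An overlapping gene was present for 36.7% of the affected genes and 23.2% of the others (odds ratio 1.91, interval 1.45 to 2.51), so that overlap may account for part of them but not for most. How the estimates came to be 0 in the remainder stays open, and no biological explanation was tested.

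Ddx3y and Uty, on the Y chromosome from 597158 to 623056 and from 433304 to 582202, were near 0 in both libraries labelled as overexpressing with a normal counterpart. Failed estimates do not account for this, since 0 of the 4 values were exactly 0. An exchange of the normal and overexpressing labels stays open, since the log2 ratios of Hk2 between them, 0.3662 and 0.2426, were below 2-fold and do not settle the labels. Eif2s3y, at 346986 to 365290 on the same chromosome, kept 47.1% and 65.5% of the normal mean in these libraries, so a deletion of neighbouring Y genes may be involved, which was not tested. At 40 days Ddx3y, Uty and Eif2s3y stood at 15.2%, 10.5% and 13.2% of the normal mean. Y-bearing cells added to a population like the other overexpressing libraries would have raised Eif2s3y, which was instead 0.282 times the lower of them. A population of another origin at 40 days stays open as a hypothesis, as does a difference in origin between the labelled cell types, and neither was tested.

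LIF targets were low after the 24 hour withdrawal although the label says that LIF was added. Library scaling or depth does not account for this, since the reference genes had medians of 0.062 and -0.072, and failed estimates do not, since the targets never at 0 still had medians of -1.40 in normal and -2.03 in overexpressing cells. In overexpressing cells the 16 targets never at 0 had a median log2 difference of -0.79 from their level at 40 days without LIF (quartiles -1.48 and 0.19), with 11 of 16 at or below that level. That LIF signalling was not restored at harvest stays open, as a hypothesis found and tested on the same libraries. The comparison cannot decide it, because the 40 day library also differed widely in endoderm, naive and ATF4 genes. Its levels of LIF targets may therefore not reflect the absence of LIF alone. The time between addition and harvest is not given in the sources used here.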
